A study of Mus musculus with 18 samples.

How the data were processed

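Per the labels, spleens of ICR mice aged 10 weeks gave 18 RNA libraries, 3 in each of 6 groups: control, AOS at 10 mg/kg, HFD, HFD with AOS, HFD with FMT from AOS donors and HFD with FMT from control donors. RNA was extracted with Trizol and the PureLink kit, and 1 ug of total RNA went into each Illumina library. The labels do not say which animal, cage, day, hour or batch each library came from.

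The authors aligned reads with Bowtie 0.12.2 to mm10 and deposited a single table of 19326 rows and 18 columns, whose values of 2 decimals were read as FPKM from the values themselves. The unit, the counting program, the annotation and any filter are not given in the sources used here, and the column headers give only a group code and a number, by which columns were matched to the labels. The unit was checked on the values: sums of value times transcript length, for the 97.1% of rows with a length, varied by 0.79% between libraries (coefficient of variation), against 7.55% for plain column totals. This is what FPKM or RPKM give, and the 2 cannot be separated by this check. Of the rows, 401 were at 0 in all 18 libraries, 6 carried a duplicated symbol and 26 carried a symbol turned into a date by a spreadsheet. Rows for mitochondrially encoded genes and for variable and constant gene segments of antigen receptors were too few to test, so antibody transcripts and the mitochondrial share are not analysed here.

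Counts cannot be recovered from the values, and the absolute depth is unknown. The smallest nonzero values of 179 olfactory receptor genes, within a window of 0.06 to 0.1 FPKM, gave a mean step of 0.0747 to 0.0869 FPKM per library from 9 to 19 genes. The relative depth, the median step over each library's step, was 0.96 to 1.11. Only values inside the window entered the mean step, so the window keeps this range narrow. It cannot show that depths were alike. No counting error is attached to single values, since the depth is unknown.

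Values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM in at least 1 group were tested, 12969 in all. Group differences were tested with limma 3.58.1 (trend and robust variance; statmod 1.5.0) in R 4.3.3, from 1 fit to all 18 libraries with 12 residual degrees of freedom. P-values were adjusted by the method of Benjamini and Hochberg at 0.05, within each comparison. The comparisons were HFD against control, AOS against control, each treated group on the diet against HFD and against control, AOS-FMT against control-FMT, the interaction of AOS and diet, and an F test over the 6 groups. Of 50 lists of marker and pathway genes 45 could be tested, with camera at a preset correlation of 0.01. An estimated correlation between genes was run beside it, and so was fry, whose p tests whether the genes of a list on balance move in 1 direction. Summaries and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions and lengths came from GENCODE vM21 on GRCm38.

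The groups, comparisons, tests, thresholds and the 50 lists were fixed before the data were examined. Lists of liver, testis, kidney, clock phase, MHC class I and plasmacytoid dendritic cell genes were added later. Fixed in advance too was the rule for named genes. It took the 10 largest rises and 10 largest falls past adjusted p 0.05 with groups that did not overlap and a higher mean of at least 2 FPKM, leaving out antigen receptor segments and provisional symbols. Where none passed, the 3 smallest p were taken. From each list past its test, or with at least 3 genes called, the 2 members with the smallest p were added. A few genes the rule selects are not reported here.

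Slopes of treatment effects on the diet effect were fitted across the tested genes. Their spread was taken from 9 pairs of libraries, which reuse the same 6 and are not independent. The exact permutation p came from the 10 splits of the 6 libraries. Correlations between marker genes of other tissues were given as Pearson r and Spearman rho with 100000 permutations.

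The methods were tested on simulated data, with 200 genes changed in each of 20 draws. With independent genes, 58.1%, 92.6% and 98.9% of changes of 0.5, 1 and 2 on the log2 scale were found, with a median of 9 false calls (at most 15). With the residuals of these libraries shuffled, 55.3%, 91.6% and 98.5% were found, with a median of 0.5 false calls and up to 3760 in a single draw. A list of 13 genes shifted by 0.5 between AOS-FMT and control-FMT was found by camera in 20 of 20 draws under both kinds of noise. On average 0.1 other lists were called with independent genes and 15.1 with the shuffled residuals. With an estimated correlation the list was found in 20 draws with independent genes, in 2 draws with the residuals, and no other list was called.

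The replicate number was used as a block beside a comparison only where residuals of libraries with the same number went together. That held for HFD+AOS against HFD, where the correlations of the 3 pairs were 0.236, 0.268 and 0.191. The labels do not say that equal numbers share a cage or day. With the block, 33 genes passed there, and the other 3 splits that part the 3 pairs gave 0 genes each.

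Alternatives fixed in advance were quantile normalization, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, limma without robust variance, array weights, a fit to the compared groups alone, the replicate block and leaving out each library. Alternatives chosen after seeing the data were scaling by median ratios, leaving out 4 libraries high in transcripts of other tissues, and a pancreas covariate. List medians without each library were computed later, for the lists past camera. No library was left out of the values reported first.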

Results

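Spleen RNA of ICR mice, an outbred stock, aged 10 weeks was sequenced in 6 groups of 3 libraries. The groups were controls and mice dosed with AOS (read here as alginate oligosaccharide, a short-chain product of a seaweed polysaccharide) at 10 mg/kg, and 4 groups on a high fat diet (HFD). Of these, 1 had the diet alone, 1 had AOS as well, and 2 received FMT (read here as faecal microbiota transplantation), from AOS donors (AOS-FMT) or from control donors (control-FMT). Values were read as FPKM, fragments scaled to transcript length and library size (or RPKM, the same for reads), for 19326 gene symbols, of which 18925 were above 0 in at least 1 library and 12969 reached a mean of 1 in at least 1 group. Column totals ran from 627964 to 831448 FPKM, between 12221 and 12898 genes per library reached 1 FPKM, and the absolute number of reads behind each value is unknown. Values of 179 olfactory receptor genes within a window of 0.06 to 0.1 FPKM gave relative depths of 0.96 to 1.11 among the 18 libraries. From 9 to 19 such genes contributed per library. The window keeps this range narrow, so it cannot show that depths were alike. Haemoglobin transcripts took 10.8% (HFD replicate 3) to 34.4% (control replicate 1) of all FPKM. P-values given here measure the spread between these samples, since the labels do not say that the 3 libraries of a group came from separate animals. Those of limma use a spread pooled over all 6 groups, and the groups differed in spread. The mean of neutrophil granule precursor genes had an SD of 2.12 in controls and 0.13 to 0.785 elsewhere. That of erythroid genes had 0.12 in controls and 0.77 on HFD. Pooling can make p too small where the compared groups vary more than the rest.

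The comparison of HFD with control asked what the diet changed in the spleen. Of 12969 genes, 357 passed an adjusted p of 0.05, 189 higher and 168 lower on the diet. Genes expressed by T cells were among the rises. *Foxp3*, the transcription factor of regulatory T cells, was at 6.10 ± 0.985 FPKM against 2.95 ± 1.09 in controls (mean ± SD, n = 3; log2 fold change 0.87 ± 0.2 SE, adjusted p = 0.0452). *Ctla4*, an inhibitory receptor of T cells, was at 7.62 ± 0.855 against 3.88 ± 1.22 FPKM, and the co-stimulatory receptor *Cd28* at 16.5 ± 2.08 against 9.34 ± 2.57. *Trat1* (log2 fold change 0.86), which codes for an adaptor of the T cell receptor, the phosphatase gene *Dusp2* (0.78) and *Hcst* (0.77), the adaptor of a receptor on cytotoxic lymphocytes, also rose. *Il7r*, the interleukin 7 receptor, rose by 0.74 and *Cd4* by 0.71 on the log2 scale. Genes of lipid handling were among the rises as well. *Angptl4*, an inhibitor of lipoprotein lipase, was at 16.7 ± 2.64 against 8.08 ± 1.42 FPKM, and *Acot1*, an acyl-CoA thioesterase, at 3.98 ± 0.977 against 1.66 ± 0.232. The largest rise was that of the tetraspanin gene *Tspan10* (3.55 ± 1.14 against 0.963 ± 0.201 FPKM, log2 fold change 1.19 ± 0.182 SE, adjusted p = 0.0443), and *Cyp1b1*, a cytochrome P450, rose by 0.88.

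Red cell genes fell on the diet in 2 of 3 libraries. The erythroid list averaged 6.957 and 6.604 on the log2 scale in HFD replicates 2 and 3 but 8.08 in HFD replicate 1, against 8.13 to 8.35 in controls, and haemoglobin took 11%, 10.8% and 27.4% of FPKM in replicates 2, 3 and 1. *Trim10*, required for terminal erythroid differentiation, was at 39.5 ± 21.0 FPKM against 107.5 ± 26.7 in controls (log2 fold change −1.52 ± 0.285 SE, n = 3, adjusted p = 0.0443), and *Epb42*, a protein of the red cell membrane, at 21.6 ± 9.05 against 50.3 ± 7.46. *Tmod1* (−1.29), which caps actin in the red cell skeleton, *Tmcc2* (−1.29), *Ypel4* (−1.32) and *Phospho1* (−1.54) fell with them. The neutrophil gene *Stfa2l1* fell by 1.69. The largest falls were in *Prm1* (−3.09), *Prm2* (−3.08) and *Tnp1* (−2.64), which package DNA in sperm. *Prm1* stood at 85.6 FPKM in control replicate 2, 11.3 and 6.56 in the other control libraries and at most 3.87 in each of the other 15 libraries.

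Changes of the gene lists fixed before the data were examined are given for this comparison relative to the median of all genes, which lay 0.101 above 0 on the log2 scale and at 0 after scaling by median ratios. The list test was camera with a preset correlation of 0.01. In data simulated from the residuals of these libraries, 1 list was shifted between AOS-FMT and control-FMT. In that comparison camera also called 15.1 of the other lists on average. The list test was not run on simulated data for HFD against control. For HFD against control camera called 17 of 45 lists, and fry called 16, while none passed with an estimated correlation. Counts adjusted over the list alone, here and below, correct only for the genes of that list. Those genes can move together with 1 library, so such counts are not independent support. The erythroid list lay lower by a median of −1.17, with all 19 members lower, 8 past the gene test and 16 when adjusted over the list alone (camera adjusted p = 5.85e-17, adjusted p = 0.391 with an estimated correlation). Haem biosynthesis lay lower at −0.98, with 2 of 12 members past the gene test and 11 adjusted over the list alone. *Cpox* (−0.99) and *Abcb10* (−0.89), which act in the synthesis and transport of haem, were the 2 (adjusted p = 0.391 with an estimated correlation). The cell cycle list lay lower at −0.76, with 3 of 30 past the gene test and 28 adjusted over the list alone (adjusted p = 0.447 with an estimated correlation). *Mki67*, a marker of dividing cells, was at 84.0 ± 24.6 against 152.6 ± 35.7 FPKM. The checkpoint kinase gene *Bub1b* was at 11.2 ± 1.22 against 16.7 ± 3.18. DNA replication lay lower at −0.58, with 1 of 27 past the gene test, the licensing factor *Cdc6* (−0.77; *Pole* followed at adjusted p = 0.0538), and 24 adjusted over the list alone (adjusted p = 0.456 with an estimated correlation). Genes of the Nrf2 response lay at −0.38, with the glutathione synthesis genes *Gclm* (−0.87) and *Gclc* (−0.40) past the gene test and 5 of 19 adjusted over the list alone (adjusted p = 0.391 with an estimated correlation).

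Among lists that lay higher, T cells stood at 0.57, with 5 of 13 members past the gene test and 13 adjusted over the list alone (adjusted p = 0.456 with an estimated correlation). T cell activation stood at 0.43, with 2 of 15 past and 10 adjusted over the list alone (adjusted p = 0.568 with an estimated correlation). The interferon gamma response stood at 0.38, with 4 of 20 past, 12 adjusted over the list alone and adjusted p = 0.688 with an estimated correlation. *Nlrc5*, the activator of MHC class I genes, rose by 0.75 and *Irf1* by 0.47. MHC class II presentation stood at 0.34, with 3 of 10 past, 9 adjusted over the list alone and adjusted p = 0.726 with an estimated correlation. The mean over this list overlapped between the groups, at 7.76 to 8.42 on the log2 scale in controls and 8.06 to 8.31 on HFD. *H2-Ab1* was at 1532 ± 94.9 against 1106 ± 238 FPKM and *H2-DMa* rose by 0.40. Inflammatory cytokines and NF-kB stood at 0.28, with 3 of 17 past, among them *Tnf* (0.68) and *Birc3* (0.47), 9 adjusted over the list alone and adjusted p = 0.568 with an estimated correlation. NK and cytotoxic cells stood at 0.22, where the receptor genes *Klrd1* (0.32) and *Klrg1* (0.71) rose, 4 of 12 passed adjusted over the list alone and adjusted p was 0.651 with an estimated correlation. B cells (0.32) and dendritic cells (0.32) had no member past the gene test in limma, 7 of 12 and 5 of 10 adjusted over the list alone, and adjusted p = 0.799 and adjusted p = 0.456 with an estimated correlation. *Cd79b* (566.8 ± 55.8 against 414.4 ± 84.2 FPKM), *Fcrla* (107 ± 6.63 against 76.0 ± 20.9), *Flt3* (7.88 ± 0.435 against 5.55 ± 0.620) and *Siglech* (17.0 ± 5.57 against 9.31 ± 1.78) were their members with the smallest p. The list of fatty acid oxidation and PPAR targets missed the list test (camera adjusted p = 0.075), with 4 of 19 members past the gene test and 4 adjusted over the list alone.

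Mature neutrophil genes lay at −1.64, with 1 of 11 past the gene test and 9 adjusted over the list alone (adjusted p = 0.391 with an estimated correlation). Genes of neutrophil granule precursors lay at −1.99, with 0 past the gene test in limma and 11 of 11 adjusted over the list alone (adjusted p = 0.456 with an estimated correlation). *Lcn2* was at 49.98 ± 17.5 FPKM against 417.8 ± 475, *Fcnb* at 3.11 ± 1.39 against 22.4 ± 23.2 and *Clec4d* at 1.75 ± 0.133 against 3.55 ± 1.59. Control replicate 1 carried most of these transcripts, with *Lcn2* at 952.1 FPKM against 259.2 and 42.1 in the other control libraries. The granule precursor list averaged 4.03 on the log2 scale in control replicate 3, inside the 3.65 to 4.80 of the HFD libraries. Megakaryocyte and platelet genes lay at −0.69 (1 of 14 adjusted over the list alone, adjusted p = 0.456 with an estimated correlation), with *Tubb1* at 28.4 ± 4.86 against 52.6 ± 24.1 and *Treml1* at 18.8 ± 5.62 against 33.1 ± 16.6. Oxidative phosphorylation genes lay at −0.16 (0 of 30 adjusted over the list alone, adjusted p = 0.877 with an estimated correlation), among them *Atp5b* at 415.2 ± 11.2 against 455.5 ± 21.6 and *Ndufb8* at 127.2 ± 7.75 against 153.6 ± 33.8 FPKM. The list medians that follow have the median of all genes not subtracted, and with all libraries were 0.42 for B cells, 0.67 for T cells, 0.32 for NK cells, −1.53 for mature neutrophils and −1.89 for granule precursors. On that scale megakaryocytes were at −0.59, DNA replication at −0.48, MHC class II at 0.44, the Nrf2 response at −0.28 and oxidative phosphorylation at −0.06. Without control 1, B cells (0.23), T cells (0.40), mature neutrophils (−0.76), granule precursors (−1), megakaryocytes (−0.26), DNA replication (−0.31), MHC class II (0.26) and the Nrf2 response (−0.15) moved by over 1.5 times, and oxidative phosphorylation (0.02) missed the list test. Without control 2, oxidative phosphorylation (−0.03) moved by over 1.5 times. Without control 3, granule precursors (−3.02) and oxidative phosphorylation (−0.15) moved by over 1.5 times, and NK cells (0.45) missed the list test. Without HFD 3, oxidative phosphorylation (−0.04) moved by over 1.5 times, and NK cells (0.22) missed the list test. Groups did not overlap for 19.4% of genes, against a mean of 10% by chance. Genes are not independent, so here and below an excess over 10% is not shown to lie beyond chance. All 357 genes kept their direction without control replicate 1, which is little support, since they were called in these same libraries. None passed without any 1 of 11 libraries (control 1, AOS 1 and 3, HFD 2 and 3, HFD+AOS 2, AOS-FMT 1, 2 and 3, control-FMT 1 and 2). Of all genes 1 passed without AOS 2, 29 without control 2, 585 without HFD+AOS 3, 1204 without HFD 1 and 3818 without control 3. Scaling by median ratios, a filter removed or a fit to the 6 libraries alone left 0, quantile normalization left 5 and a mean of at least 5 FPKM gave 625, and the lowest adjusted p of the 357 was 0.0443.

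**Figure D1:**
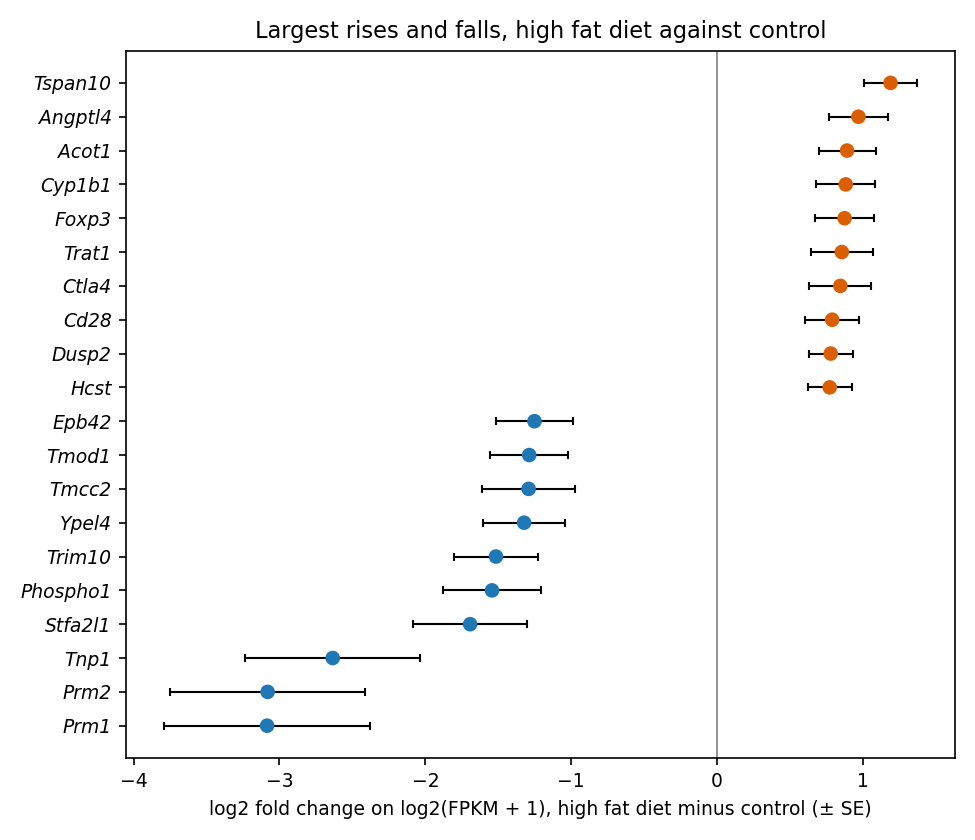
Points are log2 fold changes of the 20 genes with the largest rises and falls past adjusted p 0.05 on the high fat diet against control, on log2(FPKM + 1), and bars are ± SE of the model. Rises ran from 0.77 for *Hcst* to 1.19 for *Tspan10* and falls from −1.25 for *Epb42* to −3.09 for *Prm1*.

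**Figure D2:**
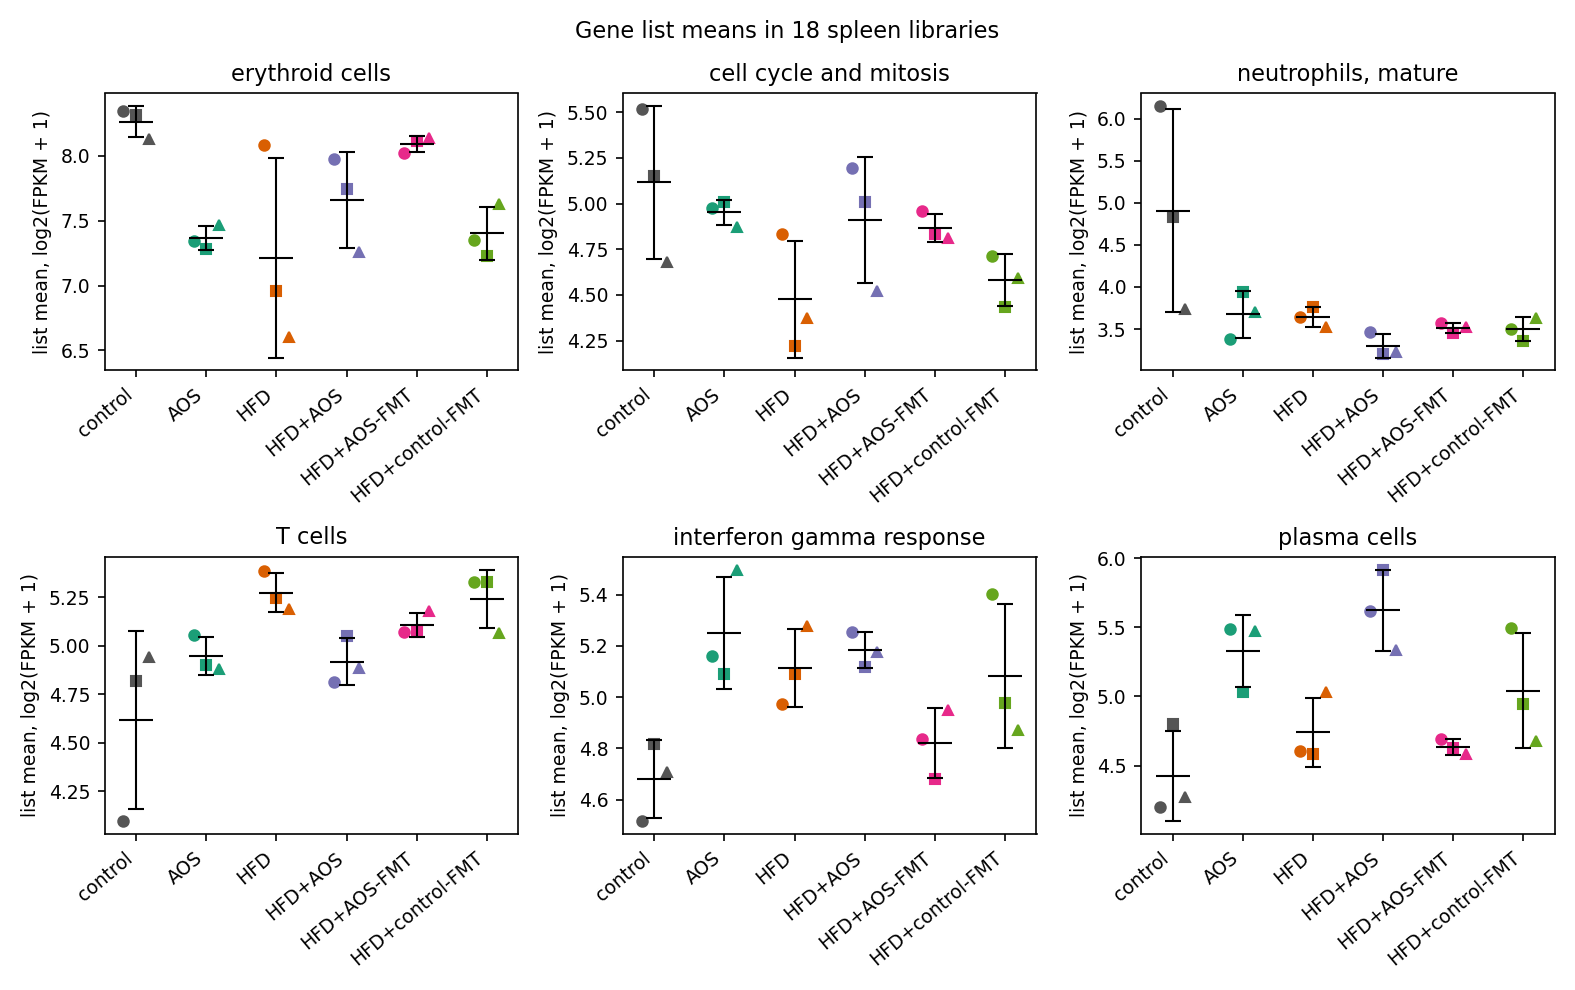
Each point is 1 library, its height the mean log2(FPKM + 1) of a list's genes, with the group mean and SD as bars (n = 3). Erythroid genes were at a mean of 8.26 in controls and 7.21 on the high fat diet, and control replicate 1 stood apart in the neutrophil panel.

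AOS against control asked what dosing alone changed. Genes of antibody-secreting cells and of the interferon response were higher in the AOS group, though no gene passed in limma (1998 at an unadjusted p under 0.05, lowest adjusted p = 0.0851). All 11 plasma cell genes lay higher, by a median of 0.87, and 11 passed adjusted over the list alone (camera adjusted p = 4.95e-10, adjusted p = 0.390 with an estimated correlation, fry adjusted p = 0.0423). *Derl3*, of endoplasmic reticulum quality control, was at 29.3 ± 7.03 against 10.8 ± 6.37 FPKM (mean ± SD, n = 3), and *Txndc5*, a protein disulfide isomerase, at 149.6 ± 30.3 against 80.9 ± 14.5. All 20 genes of the interferon gamma response lay higher (median 0.60, 16 adjusted over the list alone, adjusted p = 0.390 with an estimated correlation, fry adjusted p = 0.0423), with *Nlrc5* at 18.9 ± 2.79 against 10.2 ± 1.98 and the immunoproteasome gene *Psmb8* at 218.6 ± 26.0 against 143.4 ± 16.7. In the type I interferon response, 21 of 22 lay higher (median 0.71, 11 adjusted over the list alone, adjusted p = 0.528 with an estimated correlation), with the nucleic acid sensor *Zbp1* at 58.5 ± 27.2 against 24.2 ± 0.294. The 3 single genes with the smallest p, none past the threshold, were *Zfp296*, a zinc finger factor (10.3 ± 0.332 against 6.73 ± 0.186), *Rilpl2* (23.8 ± 2.01 against 15.5 ± 0.952) and *Manea*, a mannosidase (14.7 ± 0.897 against 10.3 ± 0.535).

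In all, camera called 20 lists for AOS, fry 3, and an estimated correlation 0. T cell activation (median 0.55, 7 of 15 adjusted over the list alone, adjusted p = 0.432 with an estimated correlation) lay higher, with the chemokine receptor gene *Cxcr3* at 19.4 ± 4.96 against 9.68 ± 2.16 FPKM and *Lag3* at 7.58 ± 1.78 against 3.43 ± 1.06. Germinal centre B cells (0.63, 5 of 8, adjusted p = 0.432 with an estimated correlation; *Fas*, *Basp1*) and the unfolded protein response (0.38, 13 of 21, adjusted p = 0.525; *Creld2* at 73.0 ± 17 against 31.6 ± 9.29, *Dnajb11*) lay higher too, the counts again being those adjusted over the list alone. So did T cells (0.31, 2 of 13, adjusted p = 0.574 with an estimated correlation; *Cd4*, *Cd3e*), NF-kB genes (0.23, 3 of 17, adjusted p = 0.574; *Tnf*, *Icam1*) and ribosomal proteins (0.17, 0 of 32, adjusted p = 0.525; *Rpl13*). Mature neutrophils (−1.15, 9 of 11, adjusted p = 0.390 with an estimated correlation; *Csf3r* at 11.8 ± 2.63 against 26.9 ± 15.1, *Clec4d*) and granule precursors (−2.01, 11 of 11, adjusted p = 0.432; *Chil3*, *Ltf*) lay lower. Erythroid cells (−0.63, 0 of 19, adjusted p = 0.432; *Tfrc*, *Epb42*) and haem biosynthesis (−0.49, 2 of 12, adjusted p = 0.432; *Cpox*, *Slc25a37*) lay lower. So did megakaryocytes (−0.50, 0 of 14, adjusted p = 0.439 with an estimated correlation; *Tubb1*, *Selp*), mast cells (−0.48, 0 of 6, adjusted p = 0.274, fry adjusted p = 0.0423; *Prss34*, *Cpa3*), smooth muscle (−0.25, 0 of 8, adjusted p = 0.574; *Smtn*, *Actg2*) and the Nrf2 response (−0.17, 2 of 19, adjusted p = 0.432; *Gclc* lower and *Slc7a11* higher). Heat shock (−0.21, 0 of 12, adjusted p = 0.697; *Hspa1a*, *Hspb1*), the cell cycle (−0.16, 0 of 30, adjusted p = 0.697; *Anln*, *Nusap1*) and DNA replication (−0.11, 0 of 27, adjusted p = 0.697; *Cdc6*, *Cdt1*) lay lower as well. Without control 1, mature neutrophils (−0.60), granule precursors (−0.96), haem biosynthesis (−0.27), megakaryocytes (−0.14), mast cells (−0.31), NF-kB genes (0.09) and heat shock (−0.54) moved by over 1.5 times, and T cells (0.03), cell cycle (0.01), DNA replication (0.11) and the Nrf2 response (−0.08) missed the list test. Without control 2, smooth muscle (−0.13), NF-kB genes (0.26) and heat shock (−0.12) missed the list test. Without control 3, T cells (0.48), granule precursors (−3.10), megakaryocytes (−0.80), cell cycle (−0.38), DNA replication (−0.29) and the Nrf2 response (−0.39) moved by over 1.5 times, and heat shock (0.01) missed the list test. Without AOS 1, heat shock (−0.09) missed the list test. Without AOS 2, type I interferon (1.16) moved by over 1.5 times, and heat shock (−0.18) missed the list test. Without AOS 3, DNA replication (−0.06), type I interferon (0.23), the Nrf2 response (−0.10) and heat shock (−0.33) moved by over 1.5 times, and NF-kB genes (0.20) missed the list test. Transcripts of other organs were lower in the AOS group as well. The testis list averaged 1.55, 3.96 and 1.08 on the log2 scale in controls against 0.22 to 0.33 with AOS, and the kidney list 1.30 to 1.49 against 0.77 to 0.84. *Kap*, a kidney gene chosen after its values were seen, was at 13.3 to 21.0 FPKM in controls and 0 in all 3 AOS libraries. Groups did not overlap for 16.8% of genes, against a mean of 10% by chance. At an unadjusted p under 0.05 in limma, 2 of the 10 splits of the 6 libraries gave at least the real 1998 genes, up to 2755. Leaving out control 3 gave 304 genes, AOS 2 gave 69, control-FMT 1 gave 17, control 2 gave 15 and HFD 3 gave 1, and the 6 libraries alone gave 1.

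HFD+AOS against HFD asked what dosing changed on the diet. Plasma cell genes were again higher, all 11 of them, by a median of 0.88 (10 adjusted over the list alone, camera adjusted p = 1.72e-12, adjusted p = 0.669 with an estimated correlation). *Sdc1*, a surface marker of plasma cells, was at 11.7 ± 2.18 FPKM against 5.07 ± 1.06, and *Prdm1*, the factor that drives plasma cell differentiation, at 5.53 ± 0.582 against 2.70 ± 0.746 (mean ± SD, n = 3). The clock-controlled factor *Dbp* was at 14.9 ± 2.05 against 7.15 ± 0.210 and the clock repressor *Nr1d1* at 8.37 ± 1.41 against 3.85 ± 0.728. *H2-Eb1*, a chain of the MHC class II molecule, was at 339.8 ± 46.5 against 75.6 ± 77.2, while 9 of the 10 genes of its list lay lower (median −0.32, 7 adjusted over the list alone, adjusted p = 0.669 with an estimated correlation), *H2-Ab1* at 1166 ± 73.0 against 1532 ± 94.9. On HFD the SD of *H2-Eb1* exceeded its mean, and why this gene went against its list was not tested. No gene passed in limma (1947 at an unadjusted p under 0.05), and with the replicate number as a block 33 passed, 13 higher and 20 lower. *Chst10*, a sulfotransferase (7.28 ± 0.635 against 15.3 ± 3.92; adjusted p = 0.0608, blocked adjusted p = 0.00902), the actin-binding *Rflnb* (13.2 ± 1.54 against 20.03 ± 0.095; blocked adjusted p = 0.0355) and *S100a10*, a partner of annexin A2 (202.8 ± 11.9 against 291.6 ± 20.1; blocked adjusted p = 0.0389), had the smallest p.

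With camera 19 lists passed, with or without the block, fry called 0 and an estimated correlation 0 (lowest blocked adjusted p = 0.685). For the lists that follow, adjusted p = 0.669 with an estimated correlation where no other value is given, and counts in brackets are those adjusted over the list alone. Cell cycle (0.43, 0 of 30; *Bub1b*, *Kif23*), DNA replication (0.35, 2 of 27; *Gins2* at 17.5 ± 3.48 against 10.3 ± 0.881, *Cdc6*) and the type I interferon response (0.47, 0 of 22; *Rsad2*, *Irf7* at 139.6 ± 65.6 against 57.1 ± 6.68) lay higher. Erythroid cells (0.47, 0 of 19; *Epb42*, *Slc4a1*) and haem biosynthesis (0.35, 0 of 12; *Abcb10*, *Fech*) lay higher. The unfolded protein response (0.18, 1 of 21; *Xbp1* at 112.3 ± 22.2 against 65.9 ± 18, *Edem1*), the circadian clock (0.19, 4 of 14), cholesterol synthesis (0.07, 0 of 21; *Sqle*, *Fdps*) and oxidative phosphorylation (0.07, 0 of 30, adjusted p = 0.759; *Ndufb8*, *Ndufa1*) did as well. T cells (−0.35, 0 of 13; *Themis*, *Cd3g*), B cells (−0.26, 0 of 12; *Fcer2a*, *Cd79a*) and heat shock (−0.83, 0 of 12; *Chordc1*, *Hsp90aa1*) lay lower. Smooth muscle (−0.53, 4 of 8; *Acta2* at 27.4 ± 5.99 against 49.2 ± 8.26, *Tagln*) and extracellular matrix (−0.17, 3 of 18; *Lox*) lay lower. Transcripts of tissues next to the spleen moved along with these lists. Exocrine pancreas genes lay higher (median 2.17, 0 of 21, adjusted p = 0.696; *Try5*, *Cela1*). HFD+AOS replicates 2 and 3 carried *Amy2a5*, pancreatic amylase, at 4366 and 1653 FPKM, against 37.4 in replicate 1. Adipocyte (−0.78, 0 of 16; *Cfd* at 16.2 ± 15 against 46.7 ± 1.89, *Cidec*) and mesothelium genes (−0.66, 0 of 8; *Msln*, *Upk3b*) lay lower. Without HFD 1, erythroid cells (0.86) and haem biosynthesis (0.64) moved by over 1.5 times, and extracellular matrix (−0.17), smooth muscle (−0.46), mesothelium (−0.49), adipocytes (−0.63), cholesterol synthesis (0.01), the unfolded protein response (0.15) and circadian clock (0.20) missed the list test. Without HFD 2, erythroid cells (0.25) and haem biosynthesis (0.23) moved by over 1.5 times. Without HFD 3, the unfolded protein response (0.43) and heat shock (−0.51) moved by over 1.5 times, and exocrine pancreas (1.08) missed the list test. Without HFD+AOS 1, erythroid cells (0.29), extracellular matrix (−0.10), exocrine pancreas (4.01), adipocytes (−0.49), DNA replication (0.22), type I interferon (0.25) and cholesterol synthesis (0.10) moved by over 1.5 times, and haem biosynthesis (0.17) and oxidative phosphorylation (0.03) missed the list test. Without HFD+AOS 2, adipocytes (−1.33) and the unfolded protein response (0.09) moved by over 1.5 times, and exocrine pancreas (0.97) and cholesterol synthesis (0.03) missed the list test. Without HFD+AOS 3, erythroid cells (0.73), haem biosynthesis (0.58) and oxidative phosphorylation (0.11) moved by over 1.5 times, and mesothelium (−0.58) and circadian clock (0.15) missed the list test. Groups did not overlap for 16% of genes, against a mean of 10% by chance. At an unadjusted p under 0.05 in limma, 2 of the 10 splits of the 6 libraries gave at least the real 1947 genes, up to 3341. Leaving out control 1 gave 22 genes, HFD+AOS 3 gave 10, control 3 gave 4, HFD 3 gave 3 and HFD 1 gave 2, and quantile normalization and median ratios each gave 2.

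HFD+AOS-FMT against HFD asked what the transplant from AOS donors changed on the diet. Red cell genes were higher after this transplant in the group means, all 19 of them, by a median of 0.83 (14 adjusted over the list alone, camera adjusted p = 2.05e-17, adjusted p = 0.794 with an estimated correlation). The AOS-FMT libraries averaged 8.02 to 8.14 over the list, and HFD replicate 1, at 8.08, lay among them, so the difference came from HFD replicates 2 and 3 (6.957 and 6.604). *Epb42* was at 40.1 ± 2.33 FPKM against 21.6 ± 9.05 (mean ± SD, n = 3). Haem biosynthesis lay higher in 11 of 12 genes (median 0.66, 9 adjusted over the list alone, adjusted p = 0.794 with an estimated correlation), with *Slc25a38* at 59.8 ± 6.31 against 38.8 ± 7.42. All 12 NK and cytotoxic genes lay lower (median −0.48, 8 adjusted over the list alone, adjusted p = 0.794 with an estimated correlation), with *Gzmb*, granzyme B, at 1.74 ± 0.110 against 4.55 ± 2.10. No gene passed in limma (1770 at an unadjusted p under 0.05, lowest adjusted p = 0.103). *Rnf11*, a ubiquitin ligase (47.3 ± 1.94 against 31.9 ± 2.41), *Tk2*, the mitochondrial thymidine kinase (28.1 ± 0.374 against 38.3 ± 2.76), and *Ttc7* (30.3 ± 1.87 against 39.5 ± 0.954) had the smallest p.

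Here camera called 15 lists, and fry and an estimated correlation 0, with adjusted p = 0.794 with an estimated correlation for each list named next unless given. Cell cycle (0.37, 0 of 30 adjusted over the list alone; *Mki67* at 125.0 ± 8.40 against 84.0 ± 24.6, *Prc1*), DNA replication (0.32, 0 of 27; *Cdc6*, *Gins2*) and heat shock (0.63, 0 of 12; *Hspe1*, *Bag3*) lay higher. Immediate early genes (0.19, 0 of 17; *Ier3*, *Dusp1*), ribosomal proteins (0.06, 0 of 32; *Rpl38*, *Rpl37*) and oxidative phosphorylation (0.03, 0 of 30, adjusted p = 0.826; *Ndufb8*, *Cox7c*) lay higher. The type I interferon response (−0.65, 0 of 22; *Rtp4* at 12.03 ± 1.87 against 28.2 ± 4.67), the interferon gamma response (−0.33, 0 of 20; *Gbp5*, *Gbp6*) and complement (−0.27, 1 of 13; *C3* at 225.1 ± 19.6 against 324.4 ± 13.6, *C4b*) lay lower. Red pulp macrophages (−0.34, 0 of 12; *Spic*, *Axl*), extracellular matrix (−0.26, 0 of 18; *Col6a1*, *Col6a2*) and adipocytes (−0.71, 0 of 16; *Pnpla2*, *Lipe*) lay lower. Without HFD 1, cell cycle (0.56) moved by over 1.5 times, and extracellular matrix (−0.26), adipocytes (−0.54), oxidative phosphorylation (0.02), heat shock (0.25) and ribosomal proteins (0.01) missed the list test. Without HFD 2, cell cycle (0.23) and immediate early genes (0.12) moved by over 1.5 times, and oxidative phosphorylation (0.02) missed the list test. Without HFD 3, interferon gamma (−0.20) and heat shock (1.01) moved by over 1.5 times, and red pulp macrophages (−0.17) and complement (−0.13) missed the list test. Without AOS-FMT 1, red pulp macrophages (−0.23), complement (−0.19) and oxidative phosphorylation (0.01) missed the list test. Without AOS-FMT 2, adipocytes (−1.12), complement (−0.44) and ribosomal proteins (0.11) moved by over 1.5 times, and interferon gamma (−0.27) and immediate early genes (−0.09) missed the list test. Without AOS-FMT 3, oxidative phosphorylation (0.07) moved by over 1.5 times, and red pulp macrophages (−0.30), adipocytes (−0.49), complement (−0.20) and ribosomal proteins (0.03) missed the list test. Groups did not overlap for 22.9% of genes, against 10% by chance. Leaving out HFD 1 gave 39 genes, AOS 3 gave 4 and HFD 3 gave 1, and the 6 libraries alone gave 1.

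HFD+control-FMT against HFD asked what the transplant from control donors changed, and 2 genes rose. *Dbp*, a transcription factor whose mRNA follows the daily clock (chromosome 7, 45705088 to 45710203 in GRCm38), was at 18.6 ± 2.59 FPKM against 7.15 ± 0.210 (mean ± SD, n = 3; log2 fold change 1.26 ± 0.170 SE, adjusted p = 0.0181). *Tmsb15b1*, a thymosin beta gene that binds actin monomers (chromosome X, 136974022 to 136976874), was at 2.28 ± 0.250 against 0.247 ± 0.245 (1.41 ± 0.197 SE, adjusted p = 0.0181), and it overlaps 2 related thymosin genes on the same strand. Clock genes lay higher in 11 of 14 cases (median 0.37, 9 adjusted over the list alone, camera adjusted p = 5.2e-11, adjusted p = 0.377 with an estimated correlation), with *Nr1d1* at 9.36 ± 0.809 against 3.85 ± 0.728 and adjusted p = 0.596. Camera called 11 lists, and fry and an estimated correlation 0. For the other 10, adjusted p = 0.926 with an estimated correlation. Germinal centre B cells (0.43, 0 of 8 adjusted over the list alone; *Rgs13*, *Basp1*), plasma cells (0.26, 0 of 11; *Fkbp11*, *Derl3*) and T cell activation (0.14, 0 of 15; *Pdcd1*, *Il21*) lay higher. Cell cycle (0.11, 0 of 30; *Plk1*, *Tpx2*) and DNA replication (0.09, 0 of 27; *Gins2*, *Tyms*) lay higher. NK and cytotoxic cells (−0.31, 3 of 12; *Klrb1c* at 1.71 ± 0.456 against 4.29 ± 2.14, *Klrg1*) and the type I interferon response (−0.33, 0 of 22; *Ddx58*, *Cmpk2*) lay lower. Smooth muscle (−0.25, 0 of 8; *Acta2*, *Actg2*), red pulp macrophages (−0.25, 0 of 12; *Spic*, *Slc40a1*) and PPAR targets (−0.09, 2 of 19; *Angptl4* at 10.0 ± 2.60 against 16.7 ± 2.64, *Cpt2*) lay lower. Without HFD 1, cell cycle (0.28) and DNA replication (0.17) moved by over 1.5 times, and plasma cells (0.18), smooth muscle (−0.30), type I interferon (−0.33), PPAR targets (−0.06) and T cell activation (0.04) missed the list test. Without HFD 2, smooth muscle (−0.23), cell cycle (−0.02) and DNA replication (0.02) missed the list test. Without HFD 3, T cell activation (0.21) moved by over 1.5 times, and red pulp macrophages (−0.12), cell cycle (0.06) and DNA replication (0.07) missed the list test. Without control-FMT 1, germinal centre B cells (0.20), plasma cells (0.04), smooth muscle (−0.18), cell cycle (0.03), DNA replication (0.02), PPAR targets (−0.07) and T cell activation (−0.02) missed the list test. Without control-FMT 2, cell cycle (0.19) moved by over 1.5 times, and red pulp macrophages (−0.22), smooth muscle (−0.23) and PPAR targets (−0.06) missed the list test. Without control-FMT 3, germinal centre B cells (0.71), smooth muscle (−0.42), PPAR targets (−0.15) and T cell activation (0.33) moved by over 1.5 times, and NK cells (−0.34) and cell cycle (0.09) missed the list test. Groups did not overlap for 10.2% of genes, against 10% by chance, and 601 genes had an unadjusted p under 0.05. No gene passed without HFD 1, control-FMT 1 or control-FMT 2, *Tmsb15b1* alone passed without HFD 2, and 3 other genes without HFD 3, where *Dbp* had an adjusted p = 0.0572 and *Tmsb15b1* an adjusted p = 0.0733. *Tmsb15b1* also missed it with a pseudocount of 0.1 (log2 fold change 3.11, adjusted p = 0.123), in the 6 libraries alone (adjusted p = 0.124) and without control-FMT 3 (adjusted p = 0.0534).

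AOS-FMT against control-FMT, both on the diet, compared the transplant with its own control. *Dbp* fell, from 18.6 ± 2.59 FPKM after control-FMT to 5.92 ± 1.22 after AOS-FMT (mean ± SD, n = 3; log2 fold change −1.51 ± 0.170 SE, adjusted p = 0.00245), and was the only gene to pass in limma (1356 at an unadjusted p under 0.05). *Nr1d1* (chromosome 11, 98767932 to 98775333) stood at 2.96 ± 1.31 against 9.36 ± 0.809 (−1.44 ± 0.224 SE, adjusted p = 0.0664). Clock genes lay lower in 12 of 14 cases (median −0.41, 9 adjusted over the list alone, camera adjusted p = 6.08e-08, adjusted p = 0.628 with an estimated correlation, fry adjusted p = 0.031). Red cell genes lay higher in 19 of 19 (median 0.70, 13 adjusted over the list alone, adjusted p = 0.628 with an estimated correlation), with the carbonic anhydrase *Car2* at 1139 ± 97.7 against 625 ± 122. Haem biosynthesis followed (0.60, 4 of 12 adjusted over the list alone, adjusted p = 0.826 with an estimated correlation; *Slc25a37*, *Abcb10*). Camera called 12 lists, fry 1 and an estimated correlation 0. Cell cycle (0.28, 0 of 30, adjusted p = 0.901 with an estimated correlation; *Mki67*, *Anln*), DNA replication (0.19, 0 of 27, adjusted p = 0.901; *Cdc6*, *Prim1*) and heat shock (0.53, 0 of 12, adjusted p = 0.901; *Hspe1*, *Hsp90aa1*) lay higher. The Nrf2 response (0.05, 1 of 19, adjusted p = 0.901; *Gclc* at 29.2 ± 0.207 against 21.1 ± 3.14, *Gclm*) and immediate early genes (0.05, 0 of 17, adjusted p = 0.929; *Btg2*, *Ier2*) lay higher, the counts being those adjusted over the list alone. Plasma cells (−0.34, 0 of 11, adjusted p = 0.929 with an estimated correlation; *Slamf7*, *Fkbp11*) and T cell activation (−0.29, 0 of 15, adjusted p = 0.901; *Pdcd1*, *Lag3*) lay lower. The interferon gamma response (−0.27, 0 of 20, adjusted p = 0.929; *Gbp2*, *Cxcl9*) and extracellular matrix (−0.17, 1 of 18, adjusted p = 0.929; *Timp1*, *Fn1*) lay lower. Liver transcripts differed between the groups, at a list mean of 2.96 ± 1.45 against 0.718 ± 0.231 on the log2 scale (SD, n = 3). Without AOS-FMT 1, immediate early genes (0.10) moved by over 1.5 times, and the Nrf2 response (0.09) missed the list test. Without AOS-FMT 2, interferon gamma (−0.21), the Nrf2 response (−0.03), immediate early genes (−0.08) and T cell activation (−0.23) missed the list test. Without AOS-FMT 3, the Nrf2 response (0.09) and immediate early genes (0.24) moved by over 1.5 times, and extracellular matrix (−0.11) missed the list test. Without control-FMT 1, heat shock (0.35) moved by over 1.5 times, and plasma cells (−0.12), interferon gamma (−0.14), the Nrf2 response (0.06), immediate early genes (0.04) and T cell activation (−0.12) missed the list test. Without control-FMT 2, the Nrf2 response (−0.01) and immediate early genes (0.08) moved by over 1.5 times. Without control-FMT 3, plasma cells (−0.52), the Nrf2 response (0.10) and T cell activation (−0.52) moved by over 1.5 times, and extracellular matrix (−0.11) and immediate early genes (0.14) missed the list test. Groups did not overlap for 23.4% of genes, against 10% by chance. *Dbp* passed without each library in turn, but not without 4 libraries high in transcripts of other tissues. The count reached 2 without AOS 3, HFD 3 or AOS-FMT 3 and 7 without control-FMT 3.

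**Figure D3:**
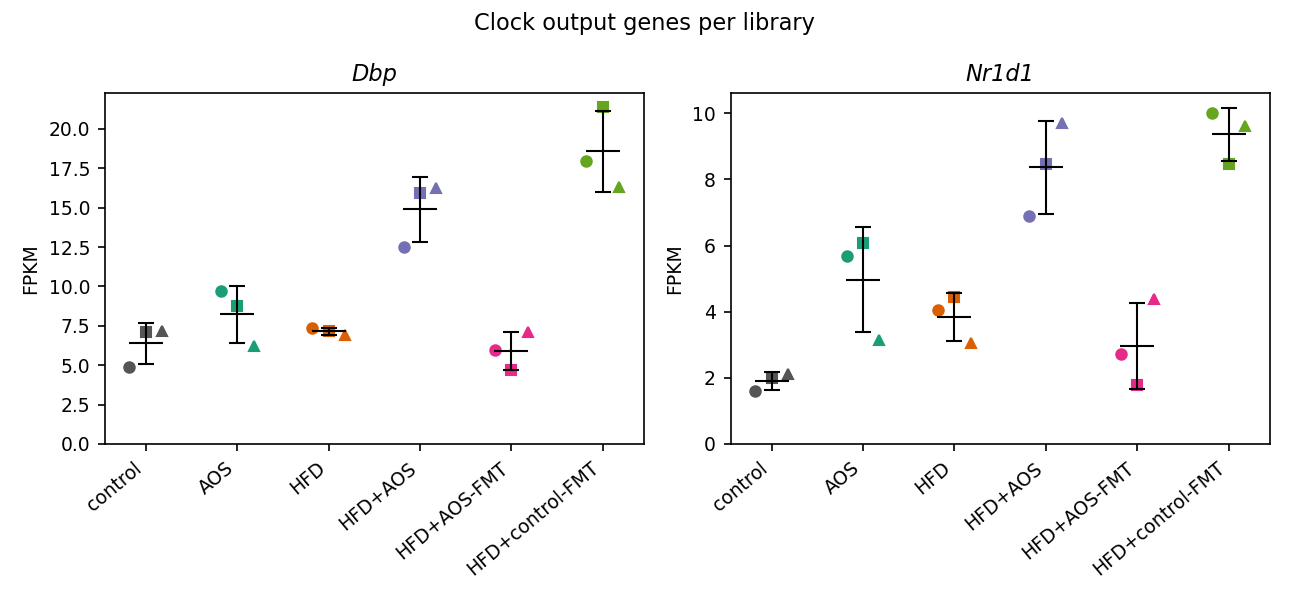
FPKM of *Dbp* and *Nr1d1* per library in the 6 groups, with the group mean and SD (n = 3). Means of *Dbp* were 18.6 after control-FMT and 14.9 with HFD+AOS, and 5.92 to 8.22 in the other groups.

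Over the 6 groups together, 15 genes passed an F test in limma. *Dbp* (adjusted p = 0.00509) and *Nr1d1* (adjusted p = 0.0168) came first, with group means of *Nr1d1* from 1.91 FPKM in controls to 9.36 after control-FMT. The others were *Tspan10*, *Cd72*, *Apol11b*, *Rflnb*, *Pltp*, *Manea*, *Runx2*, *Zfp296*, *Rnf11*, *Pfkfb3*, *S100a10*, *Acot1* and *I830077J02Rik*, of which *Cd72*, *Apol11b*, *Pltp*, *Runx2*, *Pfkfb3* and *I830077J02Rik* fell outside the rule for named genes and are named after their values were seen. *Acot1* averaged 1.66 FPKM in controls and 1.65 with AOS, and 3.53 to 4.70 in the 4 groups on the diet. *Rnf11* averaged 46.4 in controls and 47.3 after AOS-FMT, and 31.9 to 36.6 in the other groups. Without 1 library the F test passed 1060 genes (control 3), 330 (HFD 1), 176 (control-FMT 3), 130 (AOS 2), 28 (AOS 3), 25 (HFD 3), 9 (HFD+AOS 3) and 5 (control 2). It passed 3 without HFD 2 or HFD+AOS 1, 2 without AOS 1, AOS-FMT 2 or AOS-FMT 3, and 1 without HFD+AOS 2, AOS-FMT 1, control-FMT 1 or control-FMT 2. The interaction of AOS with diet had no gene past the threshold in limma (2058 at an unadjusted p under 0.05).

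Each treated group on the diet was also set against control. HFD+AOS differed in 271 genes, 234 higher and 37 lower, and 108 higher and 37 lower after scaling by median ratios. All 11 plasma cell genes rose in this comparison (median 1.27, 11 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation). HFD+control-FMT differed in 665 genes, 414 higher and 251 lower, and 193 higher and 219 lower after that scaling. In fits to the compared groups alone, almost no gene passed for HFD+AOS or for HFD+control-FMT against control. Among the 665 genes 10 of 19 erythroid genes fell (14 adjusted over the list alone), and 8 of 13 T cell genes (12), 7 of 15 T cell activation genes (12) and 6 of 14 clock genes (11) rose, each list at adjusted p = 0.368 with an estimated correlation. HFD+AOS-FMT differed in 0 genes in limma, with 1501 at an unadjusted p under 0.05. HFD and HFD+control-FMT shared 95 genes higher and 119 lower against control, where 6.03 and 3.25 would overlap if the calls were independent. Across genes the 2 sets of changes correlated with r = 0.821, inside the range of −0.29 to 0.891 (mean 0.491) of groups simulated without an effect but with the same controls. Leaving out HFD+AOS 2 gave 0 genes for HFD+AOS and control 1 gave 9, 109 and 120 passed without HFD+AOS 1 and 3, 137 without control 2, 175 without AOS-FMT 1 and 1327 without control 3. For HFD+control-FMT 5 passed without control-FMT 1, 12 without control-FMT 2 or control 1, 366 to 382 without any AOS-FMT library, 367 without AOS 1 or HFD+AOS 2 and 3104 without control 3, and for HFD+AOS-FMT 602 passed without control 3 and 2 without HFD 3.

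The series title speaks of a rescue of diet effects, and the slope of each treatment's log2 fold changes on those of HFD against control measured opposition across 12969 genes, which are not independent replicates. AOS-FMT minus control-FMT, which shares no library with the diet effect, gave a slope of −0.36 (r = −0.466 across genes), below 0 in each of 9 pairs of libraries with SD 0.126. The 9 pairs reuse the same 6 libraries and the same diet effect. They are not 9 replicates, and their SD is not an error of the slope. The exact permutation p of this slope over the 10 splits of the 6 libraries was 0.1, the smallest that 3 against 3 allow (two-sided). HFD+AOS minus HFD+control-FMT gave −0.17 (exact permutation p = 0.4), and 0.01 without HFD+AOS replicate 1. The slopes of HFD+AOS, AOS-FMT and control-FMT minus HFD were −0.26, −0.45 and −0.09, but these share the HFD libraries with the diet effect. Their r across genes was −0.306, −0.627 and −0.144, against means of −0.481, −0.431 and −0.434 in simulated groups without an effect. The simulated ranges were −0.895 to 0.652, −0.818 to 0.633 and −0.882 to 0.402, and each r lay inside its range. Of the 17 lists past camera on the diet, 13 had a median of the opposite sign in AOS-FMT against control-FMT, and 7 of these passed camera there, none with an estimated correlation (adjusted p = 0.628 to 0.929). Erythroid, haem, cell cycle, DNA replication and Nrf2 genes were higher, and T cell activation and interferon gamma genes lower. T cell activation (−0.12 and −0.23) and interferon gamma (−0.14 and −0.21) missed camera without control-FMT 1 and without AOS-FMT 2. The Nrf2 list missed it without AOS-FMT 1 (0.09), AOS-FMT 2 (−0.03) or control-FMT 1 (0.06), and reversed without control-FMT 2 (−0.01). The other 10 lists missed camera in that comparison: T cells, B cells, NK cells, dendritic cells, MHC class II and NF-kB genes with the opposite sign, and both neutrophil lists, megakaryocytes and oxidative phosphorylation with the same.

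**Figure D4:**
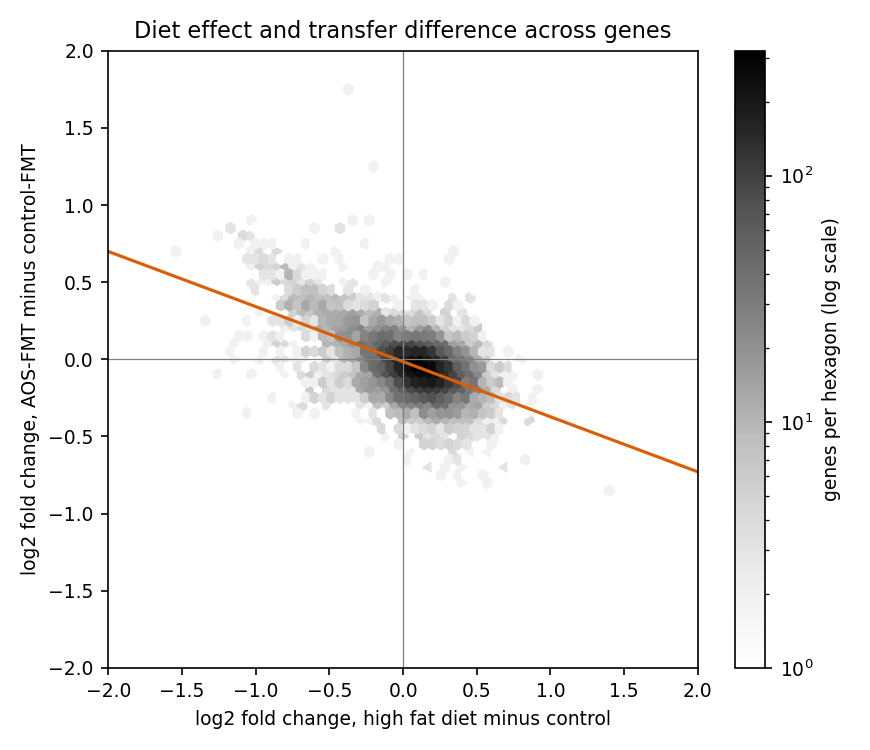
Log2 fold change of AOS-FMT minus control-FMT against that of high fat diet minus control for 12969 genes, of which 31 lie outside the plotted range; shading is the number of genes per hexagon on a log scale. The line has the slope of −0.36 across genes.

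Genes of the exocrine pancreas, liver and testis were present in some libraries of this spleen series. *Amy2a5* and *Alb* were chosen as examples after their values were seen. *Amy2a5* ran from 1.44 FPKM in control replicate 3 to 4366 in HFD+AOS replicate 2. *Alb*, serum albumin, ran from 1.01 in control-FMT replicate 1 to 166.3 in AOS-FMT replicate 2, and reached 104.6 and 98.0 in control replicates 2 and 3. HFD+AOS replicate 3 was also high in the pancreas list (7.90 on the log2 scale) and control replicate 3 in the liver list (3.82). Without 4 libraries high in such transcripts, all of replicate number 2 (control, AOS-FMT, HFD+AOS and control-FMT), left out after the values were seen, 0 genes passed for HFD against control and for control-FMT against HFD, and 2 for HFD+AOS and 6 for control-FMT against control. The log2 fold changes of *Dbp* and *Tmsb15b1* for control-FMT against HFD were then 1.16 and 1.36 (adjusted p = 0.555 for each), against 1.26 and 1.41 with all libraries. *Dbp* then missed the threshold for AOS-FMT against control-FMT (log2 fold change −1.27, adjusted p = 0.319), where 1 other gene passed.

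**Figure D5:**
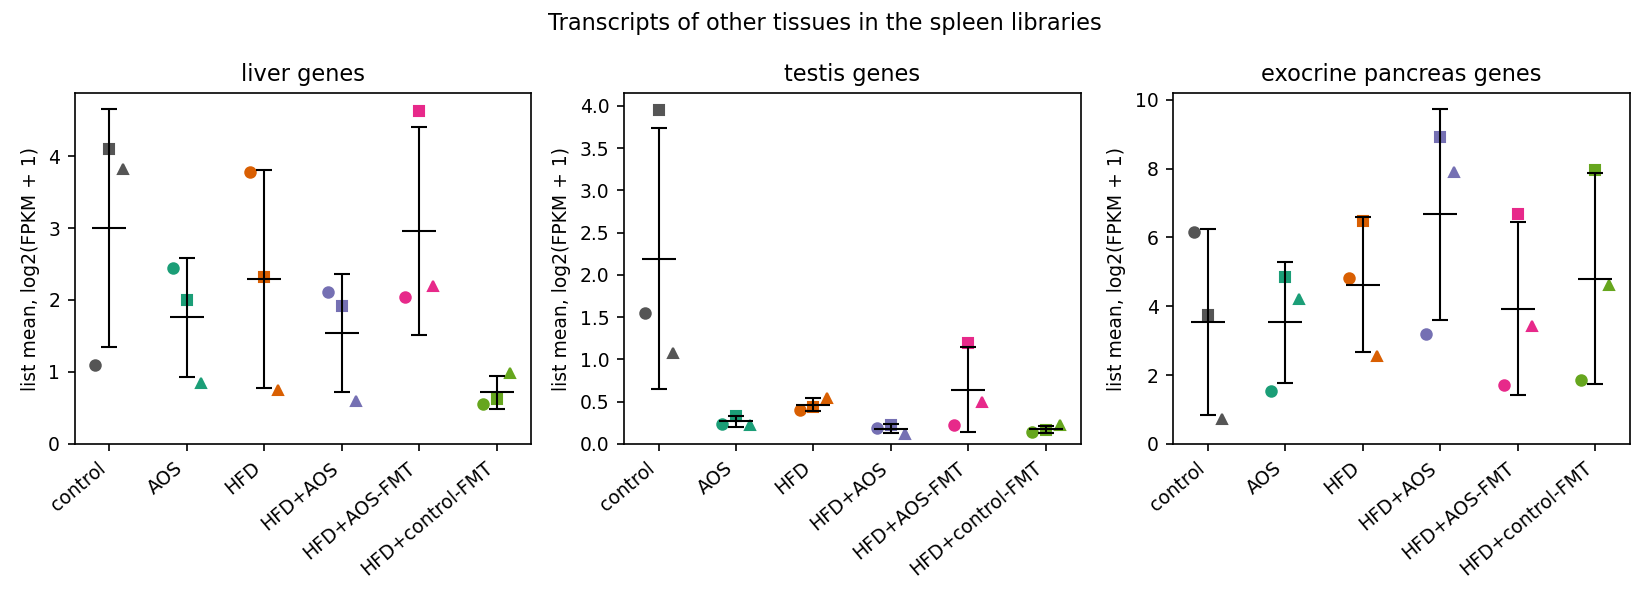
Mean log2(FPKM + 1) of liver, testis and exocrine pancreas genes, 1 point per library, with the group mean and SD (n = 3). Testis genes averaged 3.96 in control replicate 2 and at most 1.55 in any other library.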

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

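The splits of the libraries and the tests of the clock, haemoglobin, neutrophil and pancreas explanations were set before their results were seen, and those of haemoglobin on higher and lower genes apart, of 5 further clock genes, of liver RNA for *Dbp*, of liver, testis and kidney transcripts and of MHC class I genes were chosen after.

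Several gene lists stood out because the AOS effect on the diet differed from the AOS effect off it, by an interaction term in camera. The difference was positive for erythroid cells (1.119, 19 of 19 genes), haem biosynthesis (0.896), cell cycle (0.628), DNA replication (0.45), megakaryocytes (0.58), mature neutrophils (0.962), granule precursors (1.501), exocrine pancreas (2.109) and the Nrf2 response (0.104). It was negative for T cells (−0.642), T cell activation (−0.487), B cells (−0.456), germinal centre B cells (−0.681), the interferon gamma response (−0.54), MHC class II (−0.428), NF-kB genes (−0.328), ribosomal proteins (−0.189) and adipocytes (−1.535). Values are median log2 differences over the list. None of these 18 lists passed with an estimated correlation (adjusted p = 0.652 to 0.813) or with fry (adjusted p = 0.294 to 0.672). Without control 1, B cells (−0.27), granule precursors (0.54), megakaryocytes (0.19), cell cycle (0.40), DNA replication (0.24) and MHC class II (−0.25) moved by over 1.5 times, and mature neutrophils (0.32), exocrine pancreas (0.72) and the Nrf2 response (0.08) missed the list test. Without control 2, NF-kB genes (−0.32) missed the list test. Without control 3, granule precursors (2.63), megakaryocytes (0.87), exocrine pancreas (3.64), MHC class II (−0.67) and the Nrf2 response (0.23) moved by over 1.5 times, and germinal centre B cells (−0.51), ribosomal proteins (−0.17) and T cell activation (−0.47) missed the list test. Without AOS 1, exocrine pancreas (1.05) moved by over 1.5 times. Without AOS 3, NF-kB genes (−0.34) missed the list test. Without HFD 1, adipocytes (−1.35) missed the list test. Without HFD 3, exocrine pancreas (1.05) moved by over 1.5 times, and NF-kB genes (−0.36) missed the list test. Without HFD+AOS 1, exocrine pancreas (3.94) and adipocytes (−0.91) moved by over 1.5 times. Without HFD+AOS 2, exocrine pancreas (0.92) moved by over 1.5 times, and NF-kB genes (−0.36) missed the list test. Without HFD+AOS 3, the Nrf2 response (0.25) moved by over 1.5 times, and germinal centre B cells (−0.61) and T cell activation (−0.41) missed the list test. No gene passed for the interaction in limma, and 2058 had an unadjusted p under 0.05. With a real count of 0, all 100 of 100 drawn splits gave at least as many genes by construction, the highest 491, so the splits say nothing on chance here.

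The 357 genes of HFD against control had a median change of 0.55 in their own direction (SE 0.123). Scaling by median ratios, which would remove an effect of haemoglobin taking more of the control reads, kept 0.975 of it, but this says nothing, since a shift common to all genes moves the higher and the lower genes apart and leaves their pooled median. The 168 lower genes went from −0.70 (SE 0.158) to −0.80 (SE 0.184), 1.145 times their value. This cannot decide for them, since the scaling took the median of all genes from 0.101 to 0. That common shift makes lower genes more negative whatever their cause. The 189 higher genes went from 0.47 (SE 0.106) to 0.36 (SE 0.095), which is 0.769 of their value and above the bound of 0.75 by less than the SE, so haemoglobin stays open for them. Leaving out control replicate 1 with its neutrophil transcripts kept 0.815 (median 0.44, SE 0.126), above that bound by less than the SE too, and stays open in part. A pancreas covariate kept 1.004, which argues against pancreas RNA as the whole cause of the size. Each of these left 0 genes past the threshold (lowest adjusted p = 0.0578, adjusted p = 0.128 and adjusted p = 0.0524). The lowest adjusted p of the called genes had been 0.0443, and why the calls ended was not tested. A diet effect on cell composition, and an unrecorded difference between animals or days, stay open and may each contribute, with 2 of the 10 splits of the 6 libraries giving as many genes and the highest other 3103.

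*Dbp* and *Nr1d1* lay lower after AOS-FMT than after control-FMT. Liver RNA would need the opposite order, since liver genes lay higher after AOS-FMT by 2.239 on the log2 scale (SD 0.231 in control-FMT), which argues against it. An hour of collection that differed between groups, or a clock shifted by the transplant, may explain the pair of genes. The clock genes that peak against *Dbp* moved both ways, with a median of −0.015 over 3 members from −0.178 (*Nfil3*, at 6.02 FPKM in control-FMT 1 against 3 and 2.53 in control-FMT 2 and 3) to 0.142 (*Arntl*). *Npas2*, under the filter of 1 FPKM and so untested, was at 0.67 to 0.98 FPKM in the AOS-FMT libraries against 0.23 to 0.40 after control-FMT, opposite to *Dbp*. Of the 7 that peak together (median −0.531), *Dbp* and *Nr1d1* are the pair itself. The other 5, *Nr1d2*, *Per3*, *Tef*, *Hlf* and *Ciart*, lay lower in each AOS-FMT library than in any control-FMT library (median −0.526, from −0.636 to −0.272, 0 called in limma, adjusted p = 0.0363 with an estimated correlation), and from −0.443 to −0.593 without each of the 6 libraries. Hour of collection is not given in the sources used here, so the 2 cannot be told apart.

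Transcripts of other organs rose together in single libraries. Liver genes followed *Alb* across the 18 libraries with a median r of 0.973 (Spearman rho 0.946, highest permutation p = 0.011 for r over 15 genes, adjusted p = 0.013; 0.969 without the 2 farthest libraries). Testis genes followed *Prm1* with a median r of 0.919 (rho 0.72, 11 genes; 0.71 without control replicates 1 and 2), although *Gapdhs* had rho 0.205 (permutation p = 0.41). Kidney genes followed *Kap* with 0.405 (rho 0.451, 3 genes; 0.312 without HFD replicates 1 and 2), which leaves kidney RNA open. RNA of liver and of testis may have entered some libraries, by carry-over of tissue or between samples, and this covers *Prm1*, *Prm2* and *Tnp1* among the falls on the diet; no biological explanation was tested.

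Groups of 3 against 3 give 10 splits, too few for a share under 0.05. HFD+control-FMT against HFD had 2 genes and the highest other split 0, AOS-FMT against control-FMT 1 and 0, and HFD+control-FMT against control 665 and 0, each with 1 split as large. By genes at an unadjusted p under 0.05 in limma, 4 of the 10 splits for HFD+control-FMT against HFD reached the real 601, up to 1098. By that measure the real split still came first for AOS-FMT against control-FMT and for HFD+control-FMT against control. HFD+AOS against control had 271, 2 splits as large and the highest other 2470. For AOS against control, HFD+AOS against HFD, HFD+AOS-FMT against HFD and HFD+AOS-FMT against control the real count was 0, so all 10 splits were as large, and the highest others were 0, 310, 0 and 35. The splits with 3103, 2470 and 310 genes put control replicates 1 and 2 with HFD 1, control replicates 1 and 2 with HFD+AOS 1, and HFD 1 with HFD+AOS 1 and 2. In the first 2 of these, the libraries put together held at least 27.1% haemoglobin of all FPKM, the others at most 21.5%. In the third it was at least 19.9% against at most 12.6%. This points to a structure of the samples other than the groups that follows the haemoglobin share. Its cause was not tested. For the 6 groups together 15 genes passed. Of 100 drawn splits, the real one among them, 1 was as large and the highest other gave 13. Such draws treat the 18 libraries as exchangeable, but 16 of 18 lay closest to their own replicate number. Chance was therefore not excluded for that count. The count itself was 2 with no filter, 0 without 4 libraries and 1 to 1060 without each library in turn.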

How the results depend on the processing

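Scaling by median ratios, leaving out 4 libraries and the pancreas covariate were chosen after the data were seen; the other alternatives were set before. Among called or named genes none changed direction under any setting: 5187 values kept their side of the threshold, 719 lost it and 228 crossed it. These genes were chosen from the same libraries by small p or by groups that did not overlap. A change of direction was therefore unlikely from the start, and its absence is little support. *Dbp* in AOS-FMT against control-FMT kept its call in 28 of 29 settings, all but that without 4 libraries, *Dbp* in control-FMT against HFD in 23 of 29 and *Tmsb15b1* in 20 of 28. The named genes called for HFD against control kept theirs in only 9 to 11 of 28 or 29 settings. Counts of genes below follow the order HFD, AOS, HFD+AOS over HFD, AOS-FMT over HFD, control-FMT over HFD, AOS-FMT over control-FMT, then HFD+AOS, AOS-FMT and control-FMT over control, interaction and F test. Array weights, which ran from 0.168 to 31.8 and did not converge, gave 7979, 4932, 6020, 3224, 280, 650, 8918, 4500, 6238, 6205 and, for the F test (any group: genes changed), 11355. A fit to the compared groups alone gave 0, 1, 1, 1, 1, 4, 1, 0 and 2 for the first 9. Quantile normalization gave 5 for HFD and 2 for HFD+AOS over HFD. No filter gave 0 for HFD, 379 for control-FMT over control and 2 for the F test. A mean of at least 5 FPKM, with fewer genes tested, gave 625 for HFD, 1 for HFD+AOS over HFD, 1 for control-FMT over HFD and 38 for the F test. A pseudocount of 0.1 gave 1 for control-FMT over HFD and 36 for the F test. The replicate block gave 1842 for HFD, 33 for HFD+AOS over HFD, 2 for AOS-FMT over control-FMT, 1468 for control-FMT over control and 210 for the F test; 16 of 18 libraries lay closest to their own number, a hint from the data alone. Median ratios gave 0 for HFD, 2 for HFD+AOS over HFD, 145 for HFD+AOS over control and 412 for control-FMT over control. Without 4 libraries the counts were 0 for HFD, 1 for AOS, 1 for AOS-FMT over HFD, 0 for control-FMT over HFD, 2 for HFD+AOS over control, 6 for control-FMT over control and 0 for the F test. The pancreas covariate gave 0 for HFD, 1 for HFD+AOS over HFD and 57 for the F test. Leaving out each library gave 0 to 3818, 0 to 304, 0 to 22, 0 to 39, 0 to 3, 1 to 7, 0 to 1327, 0 to 602, 5 to 3104, 0 to 0 and 1 to 1060. Lists past camera ran from 16 to 23, 17 to 23, 13 to 24, 11 to 18, 8 to 17 and 10 to 18 in the first 6 comparisons, 83 to 110 in total. With an estimated correlation they were 0 in each of the 6 and in total, and fry gave 3 for AOS, 0 for HFD+AOS, AOS-FMT and control-FMT over HFD, 1 for AOS-FMT over control-FMT and 20 in total. The opposition slopes ran without each library from −0.459 to −0.197 (AOS-FMT minus control-FMT), −0.312 to 0.006 (HFD+AOS minus control-FMT), −0.404 to −0.061, −0.56 to −0.298 and −0.23 to −0.007 (HFD+AOS, AOS-FMT and control-FMT minus HFD). Over the genes of the F test alone they were −0.644, −0.621 and, reversed, 0.292 for AOS-FMT minus control-FMT, HFD+AOS minus control-FMT and control-FMT minus HFD. Except for the mean of 5 FPKM and the fits to fewer libraries, the cause was not tested. Depth is unknown, so what it limits cannot be given. The relative depths of 0.96 to 1.11 were kept narrow by the window of values used.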

Other observations

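The lists of MHC class I genes and of plasmacytoid dendritic cells, and their tests, were chosen after the data were seen. All 16 genes of MHC class I presentation lay higher on HFD than in controls (median 0.51, 7 called, adjusted p = 0.233 with an estimated correlation, fry adjusted p = 0.0049), and 4 of them are also in the interferon gamma list. Medians against control were 0.60 with AOS (0 called in limma, adjusted p = 0.0595), 0.56 with HFD+AOS (6 called), 0.31 after AOS-FMT (0 called) and 0.54 after control-FMT (8 called). AOS dosing may raise the list, at 0.599 without the diet against 0.016 on it, so the hypothesis stays open. Of 10 plasmacytoid dendritic cell genes, *Klk1* followed the pancreas list across libraries (r = 0.895, rho 0.808), so it was left out. The other 9 stood at 0.58 on HFD (0 called in limma, adjusted p = 0.182 with an estimated correlation), 0.67 with HFD+AOS (3 called, adjusted p = 0.0513) and 0.75 after control-FMT (7 called, adjusted p = 0.0513) against control, with 0.34 for AOS (0 called, adjusted p = 0.152) and 0.49 after AOS-FMT (0 called, adjusted p = 0.0513); *Siglech* and *Ccr9* are also in the dendritic cell list. On HFD the median was 0.33 without control 1, and 4 were called without control 3. With HFD+AOS 0 were called without control 1 or HFD+AOS 2 and 6 without control 3. After control-FMT 0 were called without control-FMT 1, 1 without control 1 and 2 without control-FMT 2. For the slope of −0.357, the highest of the other 9 splits reached 0.224 in size, and a reversal of the diet effect by AOS-FMT may be 1 reading that 10 splits cannot settle. Haemoglobin took 21.5% to 26.4% of FPKM after AOS-FMT and 15.4% to 18.8% after control-FMT. It took 21.5% to 34.4% in controls and 10.8% to 27.4% on HFD. The slope was not computed without red cell genes, so it cannot tell a reversal from a difference in red cell content.

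No comparison passed the list test for endothelial cells (lowest adjusted p = 0.139), the glucocorticoid response (lowest adjusted p = 0.193), marginal zone macrophages (lowest adjusted p = 0.0658), monocytes (lowest adjusted p = 0.0908), replication-dependent histones (lowest adjusted p = 0.0615), skeletal muscle (lowest adjusted p = 0.204) or spleen stroma (lowest adjusted p = 0.0554), all in camera. Lists of LXR targets (adjusted p = 0.0473 for HFD+AOS and 0.0433 for control-FMT), fatty acid synthesis (median −0.16 after AOS-FMT, adjusted p = 0.0039) and p53 (adjusted p = 0.0204 after AOS-FMT) passed camera only against control, and none with an estimated correlation.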
